A study of Drosophila melanogaster with 65 samples.

How the data were processed

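Long RNA was sequenced in 24 libraries, small RNA in 24, histone marks by Cut&Run in 8 and chromatin immunoprecipitation in 9. The material was whole ovaries of Drosophila melanogaster and OSS cells, a line of somatic sheath cells from the ovary. Of the long RNA libraries, 12 came from OSS cells given siRNA against GFP (the control), Piwi, Traffic jam (TJ) or Cubitus interruptus (Ci), 3 libraries each. The other 12 came from ovaries of 6 fly lines named FITS, FlamBG, FlamKG, FPSE1, FPSE2A and FPSE2B in the labels, each with 1 mutant and 1 wild-type library. The labels and series text tie the lines to alleles at the flamenco locus, and what each line carries is not given in the sources used here. The labels do not say that replicates were separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

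Per the submitters' processing notes, DESeq2, FastQC, Bowtie2 and MACS2 were used, with no role or version given. Per the labels, long RNA libraries came from a ribosomal RNA depletion kit, and small RNA libraries from a kit for small RNA. The deposited long RNA tables held whole-number counts of uniquely mapped reads per gene, sense and antisense apart, for the whole locus and for its parts, per the file headers. They also held counts over all positions and a normalised column, which was not used here. The ovary small RNA tables held RPM (reads scaled to library size) per miRNA arm and library, as made by the authors, per the file headers. The OSS small RNA tables held RPM deposited as 1 value per knockdown for the 3 replicates together. The Cut&Run lists held summits, each with a −log10 q at the summit, per the file headers. Those scores are the authors' and were used to rank and match summits within a list, and their medians are given per library. The ChIP data came as 1 deposited list of TJ peak positions, each 500 bp wide, with no other value. Genome positions are on dm6 (Release 6), as judged from the positions of genes in the tables.

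Each long RNA table listed 16369 genes. Of these, 12346 matched a symbol of the reference table, and 91.1% of those had the same start and end there. Start or end differed between libraries for 756 genes in OSS cells and 495 in ovaries, and such genes are called uncertain where named. Reads that mapped to several positions were left out of the unique counts, so genes with near-identical copies, such as those of Hsp70, are uncertain too. No value column belonged to a sample outside the series, the number of such columns being 0.

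Counts of unique sense reads over the whole locus were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr and libraries were scaled by TMM. CPM are counts scaled to the TMM library size, given as mean ± SD. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. All 12 OSS libraries shared 1 fit without a term for the replicate number. In ovaries the fit had the line as a block, because the labels give each line a mutant and a wild-type library. Lists of genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over all lists and comparisons of a tissue, and again with the correlation estimated.

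Replicate numbers 1, 2 and 3 occur in every OSS group, and the labels do not say what they share. Whether they pair the samples was decided before calls were compared. Deviations from the group means correlated in all 18 same-number pairs, with r from 0.25 to 0.90, and the rule set for pairing was r above 0.1 in each pair. A fit with the replicate number as a block, called the paired fit, was therefore set beside the other. It lowered the biological coefficient of variation from 0.76 to 0.455. In ovaries r between the 2 libraries of a line was 0.21 in FITS, 0 in FlamBG, −0.05 in FlamKG, 0.39 in FPSE1, 0.23 in FPSE2A and 0.36 in FPSE2B.

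The procedures were tested on simulated counts drawn from the real means and library sizes, with 50 genes changed by each fold. The changed genes were drawn from those with high mean counts, so the shares found do not cover low genes. Counts were drawn from the model that was then fitted, so false calls do not measure errors where the real data depart from it. Without pairing, the OSS test of 10234 genes found 0% of 2-fold, 34% of 4-fold, 72% of 8-fold and 88% of 16-fold changes, with 4 false calls. With pairing, the OSS test of 10276 genes found 18%, 92%, 96% and 96% of those folds, again with 4 false calls. The ovary test of 10801 genes found 14%, 66%, 78% and 92%, with 6 false calls.

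The design expected counts for miRNAs. The ovary tables held RPM, so miRNAs with a mean of at least 10 RPM were tested with limma on log2(RPM + 10), a scale that understates changes of low miRNAs. The OSS values were pooled, so they were compared as ratios with no test, among miRNAs at 100 RPM or more in at least 1 of the 4 groups. A single ovary line was compared by log2 ratios with a prior of 1 CPM among genes with at least 20 CPM in the higher library. The median of a list there was placed among 10000 random lists matched on level in 20 bins. TJ peaks within 1 kb of an annotated gene start were set against called genes by 2-sided Fisher's exact tests. Summits of the same mark within 250 bp counted as shared. Intervals are exact 95% binomial intervals unless named otherwise and cover counting error only, since reads without molecular identifiers are not independent molecules. Calculations outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

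Tests, gene lists and most alternatives were fixed before the data were examined. The genes named are the knocked-down genes and flam in every sample, 2 to 4 members of each list by lowest adjusted p (or highest level where none passed), up to 10 highest and 10 lowest changes per comparison among genes past the threshold with at least 5 CPM and groups that did not overlap, and 3 highest and 3 lowest per ovary line. For peaks they are those at flam, tj, piwi and the piRNA lists, and the strongest of each list of peaks. Any other gene is said to have been chosen after its values were seen. The lists covered targeted genes, the flamenco locus with its neighbour, piRNA biogenesis in somatic cells, piRNA-guided nuclear silencing, germline piRNA factors, germline markers, follicle cell markers, eggshell and yolk genes, the Hedgehog pathway, the ecdysone response, heat shock, innate immune effectors, the siRNA pathway, DNA replication and cell cycle, apoptosis, the CncC oxidative response, muscle markers, and hemocyte and fat body markers. The apoptosis list had 9 of 10 names in the tables, the symbol W being a second name of hid. Transposon lists of 25 and 19 names had 0 members each in the gene tables, so transposons were not analysed here.

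Each measure over the 6 ovary lines was screened for a library far from the others by Dixon's test, and each comparison was repeated over other splits of its libraries. Alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, fits of only the compared groups, the paired fit, leaving out each library or line, other pseudocounts, windows and overlaps. Chosen after seeing the data were fits without the pair of libraries siPiwi 2 and siTj 2, DESeq2 with pairing, counts over exons, counts that include reads with several positions, and only genes with the same bounds in every library. Cut&Run after siPiwi was not analysed here. For 1 Cut&Run library per knockdown and for pooled miRNA values there was no replicate check.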

Results

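The series measured RNA and chromatin in Drosophila ovaries and in OSS cells to ask how the transcription factor Traffic jam (TJ) and the flamenco locus act in the piRNA pathway of ovarian somatic cells. In OSS cells, siRNA against GFP, Piwi, TJ or Cubitus interruptus (Ci) was followed by long RNA sequencing, with 3 libraries per group. Replicates 1, 2 and 3 held 9075806, 54359738 and 36288204 unique sense reads in genes in siGFP, 24444477, 17967875 and 14864132 in siPiwi, 19942839, 32380236 and 14001226 in siTj, and 45007471, 16427799 and 12924441 in siCi. Reads antisense to genes made up 4.07% to 5.08% of unique reads in 10 of these libraries, 12.36% in siPiwi 2 and 9.27% in siTj 2. Mutant and wild-type ovary libraries held 66915056 and 81892058 in FITS, 14786435 and 9676965 in FlamBG, 70411936 and 64242858 in FlamKG, 50551693 and 48294141 in FPSE1, 49132455 and 52757099 in FPSE2A, and 33183727 and 39846068 in FPSE2B.

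The knocked-down genes were examined first. piwi encodes the nuclear Argonaute protein that silences transposons through piRNAs. It was at 761 ± 125 CPM in siGFP cells (SD, n = 3 in each group), 88.3 ± 46.9 after siPiwi (11.6% of siGFP), 201 ± 100 after siTj (26.4%) and 668 ± 235 after siCi (87.8%). The 3 siPiwi libraries held 113, 34.2 and 118 CPM of piwi against 721, 661 and 902 in siGFP. tj, which encodes a Maf family factor of gonadal somatic cells, was at 1450 ± 507 CPM in siGFP cells and 460 ± 210 after siTj (31.7%). Its siTj libraries held 569, 218 and 594 CPM against 2030, 1100 and 1210 in siGFP. In siPiwi cells tj was at 1600, 372 and 839 CPM and in siCi cells at 2330, 789 and 881, so replicates 2 and 3 of both knockdowns lay below every siGFP library. ci, which encodes the transcription factor of Hedgehog signalling, was at 140 ± 36.6 CPM in siGFP cells and 58.6 ± 15.5 after siCi (41.9%). Its siCi libraries held 41.9, 61.6 and 72.4 CPM against 116, 122 and 182 in siGFP, so each targeted gene was lower in all 3 libraries of its knockdown than in any siGFP library. ci held 116, 83.6 and 124 CPM after siPiwi and 256, 145 and 432 after siTj, with gene bounds that differ between libraries.

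**Figure D1:**
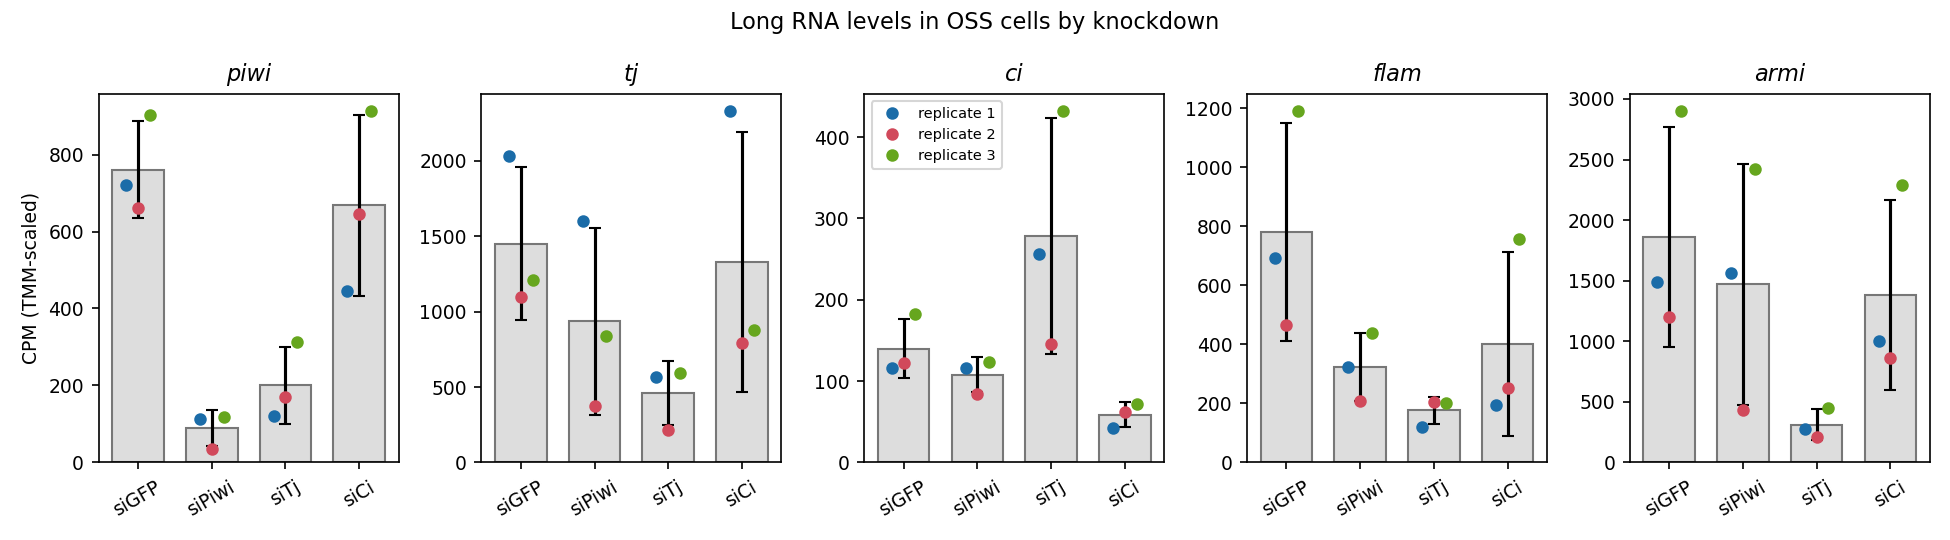
Long RNA levels in OSS cells (CPM, vertical axes) of piwi, tj, ci, flam and armi after siRNA against GFP, Piwi, TJ or Ci, with bars for the mean ± SD (n = 3) and points for libraries coloured by replicate number. flam is at 781 ± 369 CPM in siGFP and 176 ± 47.2 in siTj cells, and armi at 1860 ± 910 and 312 ± 125.

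After siTj, flam and several genes of the somatic piRNA pathway were lower than in siGFP cells. flam (X:21631891 to 21790731 on dm6), the transcript that gives rise to piRNAs against gypsy-family transposons, was at 781 ± 369 CPM in siGFP and 176 ± 47.2 in siTj cells (22.5%). armi, which encodes a helicase of piRNA biogenesis (3L:3461317 to 3466303), went from 1860 ± 910 to 312 ± 125 CPM (16.8%). fs(1)Yb, which encodes the Tudor protein of the somatic Yb bodies, went from 190 ± 19.2 to 62.9 ± 23.8 CPM (33.1%). mael, which acts in nuclear silencing, went from 142 ± 17.6 to 34.5 ± 1.08 CPM and nxf2, of the complex that silences with Piwi, from 92.1 ± 22.8 to 29.1 ± 8.92 CPM. Without pairing only mael among these passed the edgeR threshold, with a log2 fold change of −2.04 (SE 0.267, adjusted p = 0.0431), while the others had adjusted p of 0.299 (piwi), 0.533 (tj), 0.288 (flam), 0.267 (armi), 0.349 (fs(1)Yb) and 0.212 (nxf2). In the paired fit of edgeR all of them fell. Log2 fold changes there were −2.0 for piwi (SE 0.379, adjusted p = 0.0216), −1.72 for tj (SE 0.32, 0.0198), −2.03 for flam (SE 0.358, 0.0161), −2.55 for armi (SE 0.314, 0.00499), −1.70 for fs(1)Yb (SE 0.328, 0.0222), and 0.00499 was the adjusted p of mael and nxf2. DIP1, the gene next to flam, held 80.1 ± 32.7 and 78 ± 39.3 CPM.

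Some of those paired calls were lost when 1 library was left out, at fold changes of similar size. Without siGFP 1 the paired adjusted p (edgeR) was 0.0678 for piwi (log2 fold change −2.13) and fs(1)Yb (−1.95) and 0.0562 for flam (−2.05). Without siTj 1 it was 0.083 for piwi (−1.89) and tj (−1.69), 0.0636 for fs(1)Yb (−1.94) and 0.0582 for flam (−2.04), and without siTj 3 it was 0.0567 for fs(1)Yb (−1.87). armi and mael passed in each paired fit with 1 library left out, and nxf2 was not examined that way. Without pairing, the flam change was −0.46 (edgeR adjusted p = 0.799) when reads with several positions were included, and the paired fit was not run on such reads. mael lost its unpaired call in each fit with 1 library left out, where its adjusted p (edgeR) lay between 0.0563 and 0.291, while its log2 fold change lay between −2.27 and −2.12.

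Lists of piRNA genes had negative medians after siTj, with calls at the preset correlation only. Of 13 genes of somatic piRNA biogenesis 11 had negative log2 fold changes, with a median of −0.57 (camera adjusted p = 0.000695, and adjusted p = 0.562 with an estimated correlation). By gene, 0 of the 13 passed by edgeR over all genes and 3 when adjusted over the list alone. The paired fit called 3 lower (armi, fs(1)Yb and shu, at 151 ± 34.1 and 50.3 ± 20.3 CPM) and 5 adjusted over the list alone. Of 14 nuclear silencing genes 11 were negative, with a median of −0.43 (camera adjusted p = 0.0021, and adjusted p = 0.478 with an estimated correlation). There 1 was called lower (mael) and 3 adjusted over the list alone, and the paired fit called 4 in both ways (piwi, mael and nxf2 among them). Without siPiwi 2 and siTj 2 the biogenesis list kept its call (adjusted p = 0.0178) and the silencing list lost it (0.0961). Germline piRNA factors (17 tested) differed in sign by measure, with a median of 0.38, a mean of 0.16 and a camera direction of down (adjusted p = 0.131). The paired fit called 3 of them lower, with spn-E at 188 ± 6.13 and 75.5 ± 18.8 CPM and rhi at 31.6 and 9.87 CPM as examples. The list of piwi, tj and ci had a camera adjusted p of 0.108, with ci at a log2 fold change of 0.98 after siTj (edgeR adjusted p = 0.607).

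Over all 10724 genes tested, siTj lowered 5 and raised 0 by edgeR without pairing, with 788 genes (7.35%) at an unadjusted p under 0.05. DESeq2 called 211, 113 higher and 98 lower. The 5 genes, each at an adjusted p of 0.0431, were mael, dec-1, alpha-Est9, CG17732 and CG4325. dec-1, which encodes an eggshell protein, went from 601 ± 109 to 91.8 ± 42.2 CPM (n = 3, log2 fold change −2.71, SE 0.39), and the esterase gene alpha-Est9 from 244 ± 47.2 to 40.6 ± 12.4 CPM (−2.59, SE 0.385). CG17732 went from 112 ± 38 to 12.1 ± 5.22 CPM (−3.21, SE 0.443) and CG4325 from 45.5 ± 19.4 to 5.33 ± 2.27 CPM (−3.09, SE 0.455). Leaving out any 1 library other than siTj 2 gave 0 genes, and leaving out siTj 2 gave 2, of which 1 was among the 5. The paired fit called 377 genes, 221 higher and 156 lower, and all 5 fits without 1 library other than siTj 2 called fewer, with 38 genes without siGFP 1, 161 without siGFP 2, 250 without siGFP 3, 69 without siTj 1 and 100 without siTj 3. Without siTj 2 it was 358. Groups did not overlap for 912 genes above and 697 below siGFP (15%), where 10% arise by chance if the 6 libraries share no replicate effect, which would lower it.

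By the rule for named genes, 314 of the paired calls qualified, 183 higher and 131 lower. Among the highest were kst, which encodes the beta-heavy spectrin of epithelial membranes (36.4 ± 25.2 to 808 ± 228 CPM, paired log2 fold change 5.50, edgeR adjusted p = 0.0319), CG10232 (6.31, 0.00954), CG6006 (5.56, 0.0319), zye (5.02) and the Wnt ligand gene wg (0.895 to 14.1 CPM, 4.58, 0.0413). CAH2, a carbonic anhydrase gene, had the highest value (0.358 to 105 CPM, 7.34, 0.0153), with gene bounds that differ between libraries. The lowest included the Wnt gene Wnt2 (166 ± 114 to 15.2 ± 12.5 CPM, −3.26, 0.0306), CG10623 (414 ± 318 to 43 ± 22 CPM, −3.15, 0.000228), CG12147 (45.7 to 4.78 CPM, −3.15, 0.00937), CG7194 (963 to 93.4 CPM, −3.11, 0.00937) and spo, which encodes an enzyme of ecdysone synthesis (24.7 to 3.97 CPM, −2.91, 0.0117). bond, a fatty acid elongase gene whose bounds differ between libraries, went from 42.7 to 3.83 CPM (−3.24).

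Lists of stress, death and muscle genes had positive medians after siTj, with calls at the preset correlation only. All 14 heat shock genes were positive, with a median of 4.61 (camera adjusted p = 4.55e-07, and adjusted p = 0.478 with an estimated correlation). By edgeR 0 were called over all genes, 3 when adjusted over the list alone and 8 in the paired fit when adjusted over the list alone. Hsp26 was at 65.1 ± 29.6 CPM in siGFP cells and at 981, 3554 and 172 CPM in the siTj libraries (log2 fold change 4.59, SE 1.5, edgeR adjusted p = 0.425). Hsp68 was at 1860 ± 1690 CPM after siTj (3.92, adjusted p = 0.502). Reads of the Hsp70 copies are uncertain. Without siPiwi 2 and siTj 2 the list's median was 2.76 and its adjusted p 1.06e-05. Apoptosis genes (8 tested) had a median of 0.86 (adjusted p = 0.000491, and adjusted p = 0.478 with an estimated correlation), with 2 called when adjusted over the list alone. The paired fit called Ets21C (128 to 428 ± 136 CPM, edgeR adjusted p = 0.0153) and not rpr, a trigger of cell death (17.8 to 70.3 ± 13.5 CPM, 0.0602). CncC targets (13 tested, median 1.24) had an adjusted p of 0.0223 (adjusted p = 0.562 with an estimated correlation), with Keap1 (45.7 to 146 CPM) and GstE6 (17.2 to 99.2 CPM) called in the paired fit. Muscle markers (11, median 2.22) had 0.0137 (adjusted p = 0.562 with an estimated correlation), with Act57B (14 to 99.4 ± 80.6 CPM) called in the paired fit and 1 gene without pairing when adjusted over the list alone. The calls of the CncC and muscle lists were lost without siPiwi 2 and siTj 2 (0.1 and 0.0986).

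Of 19 replication and cell cycle genes 16 were negative after siTj and 0 were called without pairing, with a median of −0.49 (camera adjusted p = 0.00681, and adjusted p = 0.573 with an estimated correlation). PCNA, the sliding clamp of DNA polymerase, went from 536 ± 298 to 239 ± 79.9 CPM and was the 1 member called in the paired fit (edgeR adjusted p = 0.0478). Without siPiwi 2 and siTj 2 this list's adjusted p was 0.505. The Hedgehog list (16 tested, median 0.4) had an adjusted p of 0.055, 0.0423 in the paired fit (0.571 there with an estimated correlation) and 0.0146 without siPiwi 2 and siTj 2, with inv (11.4 to 82.9 CPM) and dpp (13.7 to 36.4 CPM) higher in the paired fit and gene bounds that differ for both. Immune effectors (9 tested, median 0.64) had 0.0814, and 0.0306 in the paired fit (0.571 there with an estimated correlation), with the cytokine gene upd3 (19.5 to 82.1 CPM) called there. Lists not past the threshold in either fit were follicle cell markers (23 tested, median 0.28, adjusted p = 0.833), where the paired fit called ct and wg higher and 3 lower with tj and bond among them, and ct went from 26.7 ± 15.7 to 281 ± 167 CPM. They were also germline markers (13, median 0.83, 0.103), ecdysone response (14, median 0.31, 0.733), the siRNA pathway (6, median −0.38, 0.207), with Dcr-2 at 461 and 248 CPM, and hemocyte and fat body markers (10, median 2.39, 0.0533), whose collagen genes Cg25C (22.6 to 213 CPM) and vkg (17.9 to 98.1 CPM, bounds differ) were called in the paired fit. Eggshell and yolk genes (13 tested) had a median of 0.5, a camera direction of down and an adjusted p of 0.6, with dec-1 called lower. The flamenco locus list held flam and DIP1 alone and had no test. Adjusted over the list alone, the paired fit called 5 germline piRNA factors lower against 1 without pairing, 4 follicle cell markers higher and 5 lower against 1 and 1, and 2 siRNA genes lower against 0. It called 5 Hedgehog genes higher against 0, 1 immune effector against 0, 5 apoptosis genes against 2, 8 CncC genes against 0, 3 muscle markers against 1 and 3 hemocyte markers against 0, and 1 replication gene lower against 0.

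After siPiwi, the log2 fold change of piwi was −3.11 (SE 0.533, n = 3, edgeR adjusted p = 0.822), −3.17 with an adjusted p of 0.0541 in the paired fit, and DESeq2 gave an adjusted p of 3.85e-07. flam was at 323 ± 115 CPM (41.4% of siGFP, log2 fold change −1.28, SE 0.543, edgeR adjusted p = 1), and its value was 0.46 when reads with several positions were included. tj (−0.63), armi (−0.34), fs(1)Yb (−0.41), shu (−0.42) and ci (−0.38) were not called. edgeR called 0 of 10724 genes, with 63 at an unadjusted p under 0.05, and DESeq2 called 3. The paired fit called 0, with 243 at an unadjusted p under 0.05, and 4 without siPiwi 2 and siTj 2. Groups did not overlap for 136 genes above and 61 below siGFP (1.84%).

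Of the lists, 5 passed after siPiwi by camera, and 0 with an estimated correlation. They were the targeted genes (adjusted p = 2.44e-06, and adjusted p = 0.26 with an estimated correlation), piRNA biogenesis (median −0.24, 0.00535), nuclear silencing (median −0.21, 0.000921), heat shock (median 2.72, 3.55e-05) and replication (median −0.25, 0.00555). The targeted and nuclear silencing lists both hold piwi, so their calls partly restate the knockdown, and neither was tested without it. piwi was the 1 targeted gene called when adjusted over the list alone, and the paired fit called 2 that way (piwi and tj) and flam in the flamenco list against 0 without pairing. Heat shock levels followed siPiwi 2, where Hsp26 was at 2216 CPM against 54.3 and 93.0 in the other libraries. Without siPiwi 2 and siTj 2 only the targeted genes passed (0.00108), and heat shock had a median of 0.15 (0.301), biogenesis 0.918, silencing 0.375 and replication 0.68. In the paired fit the eggshell and yolk list (median 1.3) passed with 0.0173 against 0.107 unpaired, and hemocyte markers (median 1.37) with 0.0225 against 0.0673, each with a paired adjusted p of 0.571 with an estimated correlation. The other lists had medians between −0.22 (siRNA pathway) and 1.71 (muscle markers) and did not pass in either fit. Wnt4, a follicle cell marker, was at 739 ± 176 CPM against 1380 ± 609 in siGFP.

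After siCi, ci had a log2 fold change of −1.26 (SE 0.402, n = 3, edgeR adjusted p = 1) that passed only in DESeq2 with pairing (adjusted p = 0.0123). ptc, which encodes the Hedgehog receptor and is a target of Ci, was at 221 ± 21.4 CPM against 396 ± 108 (−0.84, SE 0.343, edgeR adjusted p = 1). flam was at 194, 251 and 758 CPM against 694, 464 and 1190 (−0.96, SE 0.539), piwi at −0.19, tj at −0.12, armi at −0.43 and fs(1)Yb at −0.44. edgeR called 0 genes, with 83 at an unadjusted p under 0.05, and 0 in the paired fit with 412, while DESeq2 called 2. Groups did not overlap for 217 genes above and 304 below (4.86%). Heat shock genes (median 1.92, camera adjusted p = 0.000921) and piRNA biogenesis genes (median −0.32, 0.0311) passed as lists, the latter with 12 of 13 members negative, and had adjusted p = 0.562 and adjusted p = 0.573 with an estimated correlation. Targeted genes had 0.0443, and 0.0532 in the paired fit, and germline markers 0.0415 (median 0.4), and 0.0585 in the paired fit, each with an unpaired adjusted p of 0.562 with an estimated correlation. The targeted list holds ci, so its call partly restates the knockdown. The Hedgehog list had a median of −0.16 (0.179), with ci the 1 member lower in the paired fit when adjusted over the list alone, as was flam in the flamenco list, against 0 without pairing in both. The other lists had medians from −0.24 (siRNA pathway) to 0.62 (immune effectors) and did not pass.

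siTj and siPiwi were compared directly, because piwi levels were lower after both and the series asks what TJ does beyond Piwi. armi was lower after siTj than after siPiwi by a log2 fold change of −2.24 (SE 0.637, edgeR adjusted p = 0.595), and in the paired fit by −2.07 (0.0161). mael had −1.74 (0.0863, and 0.0103 paired), nxf2 −1.27 (0.0212 paired) and dec-1 −2.28 (0.174, and 0.0161 paired). piwi was higher after siTj by 1.19 without passing in either fit (0.222 paired). edgeR called 0 genes, with 353 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0863, and DESeq2 called 80, 30 higher and 50 lower. The paired fit called 73 genes, 33 higher and 40 lower. That count was 12 without siPiwi 1, 325 without siPiwi 2, 9 without siPiwi 3, 9 without siTj 1, 239 without siTj 2 and 14 without siTj 3. Unpaired, 6 genes passed without siPiwi 2 and 3 without siTj 2. Of the paired calls, 67 met the rule for named genes. The lowest included CG4325 (−3.16, 0.0119), CG17732 (−3.02, 0.0118), CG12147 (−2.69, 0.0312) and CG10623 (−2.56, 0.0016). The highest included CG9689 (3.83, 0.0103), CG9686 (3.44, 0.00931), PGRP-SA, a sensor of bacterial cell walls (3.14, 0.0473), and Ppn, a matrix protein gene (37.8 to 270 CPM, 2.64, 0.0408). Lists lower after siTj than after siPiwi were piRNA biogenesis (camera adjusted p = 0.0134) and the eggshell list (0.0434), and lists higher were Hedgehog (0.00712), heat shock (median 1.15, 0.000199), immune effectors (0.0475), apoptosis (0.000695) and CncC (0.0416). No list passed with an estimated correlation, and without siPiwi 2 and siTj 2 the eggshell (0.128), immune (0.209) and CncC (0.0903) lists did not pass. Germline piRNA factors passed in the paired fit alone (0.0437). Adjusted over the list alone, the paired fit called lower 5 biogenesis genes and 4 germline piRNA factors against 0 without pairing, and 2 follicle cell markers against 1. Higher were 3 Hedgehog genes and 2 each of immune effectors, apoptosis genes and hemocyte markers against 0. Of the targeted genes it called 2 higher and 1 lower against 1 higher, and 1 silencing gene and 1 follicle cell marker were higher against 0.

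Genes called after both siTj and siPiwi numbered 0 in the unpaired edgeR test and 2 by DESeq2. Log2 fold changes of the 2 knockdowns correlated across genes at 0.87, where 10 simulations with no change in any group, each with 3 drawn siGFP libraries shared by both comparisons, gave 0.5. Genes are not independent replicates here. The covariance was 1.15 against a simulated 0.742, and 82.7% of genes shared a sign against 66.5%. In the paired fit the correlation was 0.77 and the covariance 0.683, against 0.5 and 0.384. In the paired fit without siPiwi 2 and siTj 2 these were 0.2 and 0.185, against 0.41 and 0.241, so the excess was not present without this pair of libraries. Sharing of controls was already part of the simulations, whose highest covariance was 0.765, and 0.42 in the paired fit. An error particular to the real siGFP libraries was not tested, since they were too few to split.

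TJ binding was compared with the genes that changed after siTj. The ChIP list held 1987 TJ peaks, of which 819 (41.2%) lay within 1 kb of a gene start and 1614 (81.2%) in a gene. flam had a peak at X:21632126 to 21632625, 235 bp from its annotated start. piwi had one at 2L:10986801 to 10987300, 120 bp from its start, armi at 643 bp and fs(1)Yb at 6 bp. Peaks overlapped the starts of shu, SoYb, nxf2 and CG9754, which encodes Panoramix. The peaks nearest to mael and tj were 2815 and 9314 bp from their starts (for tj at 2L:19473581 to 19474080), and that nearest to DIP1 was at 1978 bp. Among the genes lowest after siTj, CG10623 and spo had a peak at their start, CG4325 at 131 bp and Wnt2 at 632 bp, while those nearest to CG7194, bond, CG17732 and CG12147 were 1315, 1954, 3134 and 33111 bp away. Within 1 kb, 4 of 13 biogenesis genes and 3 of 14 silencing genes had a peak, as did 1087 of all 10724 genes tested (10.1%). Of the 5 genes lower after siTj in the unpaired fit, 2 (CG4325 and dec-1) had a peak (40%, interval 5.27 to 85.3, Fisher's exact p = 0.0834). Of the 156 genes lower in the paired fit, 53 had one (34.0%, interval 26.6 to 42.0), against 9.78% of the rest (odds ratio 4.74, Fisher's exact p = 3.73e-16). Of the 221 higher, 28 had one (12.7%, exact p = 0.214). Called genes were not matched on level with the rest, so these tests do not part TJ binding from level. In the paired fit without siPiwi 2 and siTj 2 the shares were 92 of 435 lower genes (21.1%, exact p = 1.03e-10) and 36 of 309 higher genes (11.7%, exact p = 0.575). The median log2 fold change after siTj was −0.14 in genes with a peak and 0.11 in the others.

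**Figure D2:**
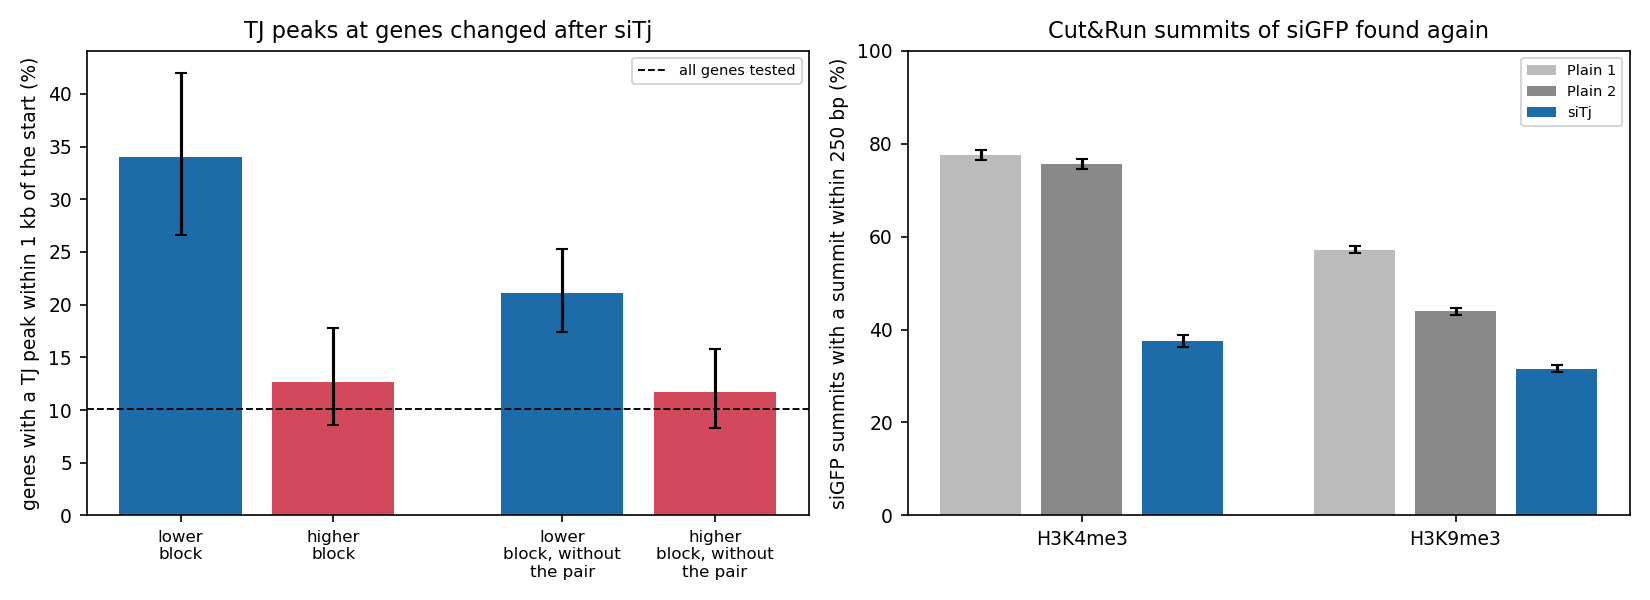
Left, percent of genes with a TJ peak within 1 kb of their start among genes lower (blue) or higher (red) after siTj in the paired fit with and without the pair siPiwi 2 and siTj 2; right, percent of siGFP Cut&Run summits with a summit within 250 bp in both Plain libraries and in siTj, with bars for the share, lines for exact 95% intervals and a dashed line at 10.1% for all genes. TJ peaks lie at 34.0% of lower and 12.7% of higher genes in the paired fit, and siTj holds 37.5% of the H3K4me3 and 31.6% of the H3K9me3 summits of siGFP.

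H3K4me3, a mark of active promoters, and H3K9me3, a mark of heterochromatin, were mapped in 1 library each for siGFP and siTj and in 2 libraries labelled Plain. H3K4me3 had 6384 and 5949 summits in the Plain libraries, 6255 in siGFP and 3134 in siTj, and H3K9me3 had 16420, 11124, 16939 and 8829. Of the siGFP H3K4me3 summits, 37.5% had one in siTj (interval 36.3 to 38.8), against 77.6% and 75.6% in the Plain libraries. Of the siGFP H3K9me3 summits, 31.6% had one in siTj (interval 30.9 to 32.3), against 57.2% and 43.9%. Conversely, 75% of siTj H3K4me3 summits and 60.4% of siTj H3K9me3 summits had one in siGFP. The median score of an H3K4me3 summit was 85.1 and 18.5 in the Plain libraries, 19.0 in siGFP and 5.15 in siTj. In the flam transcript or within 1 kb of it, H3K9me3 had 79 and 77 summits in the Plain libraries, 96 in siGFP and 49 in siTj. Counted the same way, piwi had 2 H3K4me3 summits in siGFP and 0 in siTj, and tj had 2 in siGFP and 2 in siTj. Within 1 kb of a start, H3K4me3 was found at 10 of 13 biogenesis genes in siGFP and 4 in siTj, and at 10 and 6 of 14 silencing genes. The siTj lists were shorter genome-wide for both marks, so lower counts at these places were not shown to be particular to them. The strongest H3K4me3 summit lay at 2R:1809790 in both Plain libraries, far from the nearest gene start of CG41520, and this place was also the strongest for H3K9me3 in each library, within 100 bp. Why this place led both marks was not tested, so it is not read as a promoter or as heterochromatin. tj itself held the next strongest H3K4me3 summit of the first Plain library, at 2L:19464980. With 1 library per knockdown these are differences between libraries.

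Small RNA of OSS cells was available as miRNA values pooled over 3 replicates, with no replicate check. miRNAs made up between 179875 (siCi) and 193209 (siPiwi) RPM. Among 43 miRNAs at 100 RPM or more in at least 1 of the 4 groups, mir-989 went from 8609 to 1569 RPM after siTj (log2 ratio −2.46), mir-137 from 87.68 to 20.07 (−2.07), mir-315 from 181.2 to 62.29 (−1.53) and mir-9c from 12230 to 5188 (−1.24). mir-10 (60.43 to 126.9, 1.06) and mir-1010 (47.85 to 123.7, 1.35) were over 2-fold higher. After siPiwi, let-7 went from 611.8 to 217.6 RPM (−1.49) and mir-1 from 2146 to 1068 (−1.01), and mir-1006 from 71.86 to 155.8 (1.11). After siCi, mir-1 was at −1.22. Abundant miRNAs of the lists were mir-184, at 19297 RPM in siGFP and 20163 in siTj, bantam at 18130 and 27630, mir-92b at 11270 and 15533, and mir-11 of the miR-2 family at 4770 and 7507. mir-286 of the maternal-zygotic cluster was at 401 and 323.

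In ovaries, flam was lower in the mutant than in the wild-type library in 5 of 6 lines. Its mean was 54.7 ± 38.9 CPM in mutants and 117 ± 49.9 in wild type (SD, n = 6), a log2 fold change of −1.52 (SE 0.547, edgeR adjusted p = 0.436) that did not pass. By line, mutant and wild-type levels were 51.2 and 196 CPM in FlamBG (log2 ratio −1.92), 7.01 and 54.9 in FlamKG (−2.80), 12.2 and 122 in FPSE1 (−3.22), 88.3 and 71.4 in FPSE2A (0.30), and 101 and 132 in FPSE2B (−0.38). In FITS the mutant held 68.2 CPM, at a log2 ratio of −0.85. With reads of several positions included, the log2 fold change of flam over the lines was 1.26. tj was at 119 ± 97 against 212 ± 117 CPM (−0.95, SE 0.3) and lower in 5 of 6 lines. piwi was at 198 ± 79.8 against 276 ± 112 (−0.46, SE 0.155) and lower in 6 of 6. ci (−0.34) was lower in 5 of 6 and armi (193 to 138 CPM, −0.52) in 6 of 6, and DIP1 had −0.11, none with an adjusted p below 0.436.

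**Figure D3:**
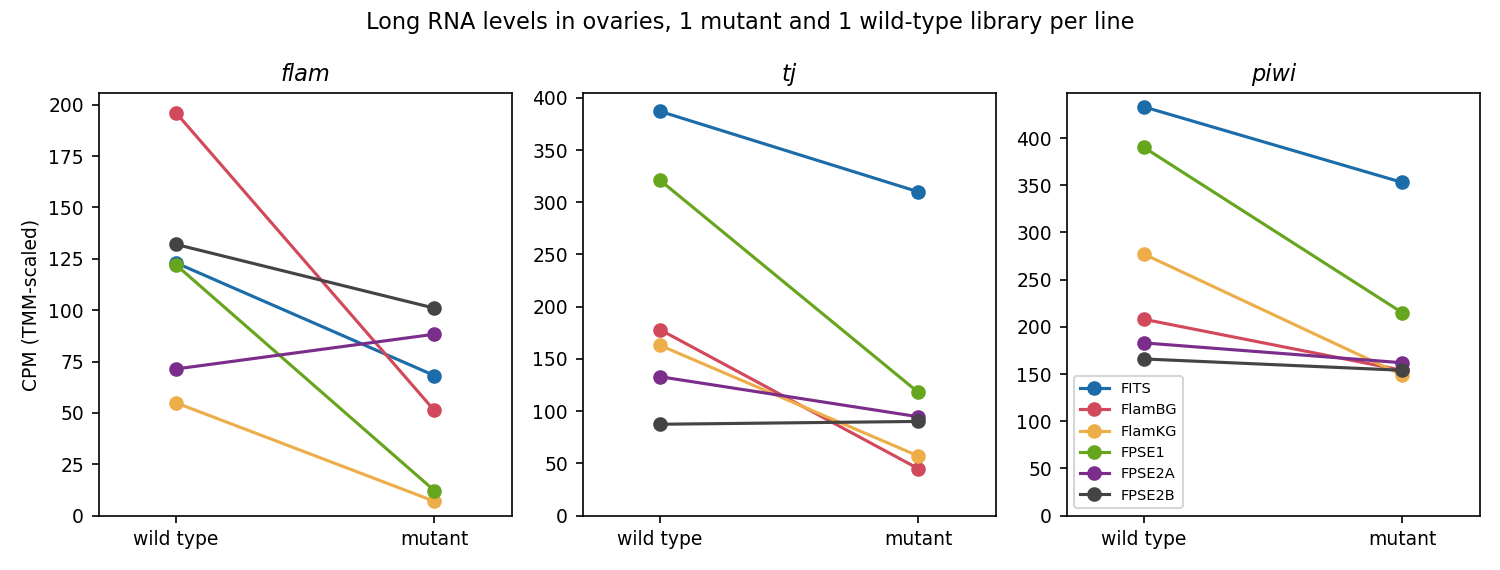
Long RNA levels (CPM, vertical axes) of flam, tj and piwi in wild-type and mutant ovaries, with 1 point per library and a line joining the libraries of each of the 6 fly lines. flam is lower in the mutant of 5 lines, down to 7.01 CPM in FlamKG, and higher in FPSE2A at 88.3 against 71.4 CPM.

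edgeR called 0 of 11155 genes between mutant and wild-type ovaries, with 1242 at an unadjusted p under 0.05 and a lowest adjusted p of 0.436, and DESeq2 called 357 (295 higher and 62 lower). As lists, 9 passed by camera at the preset correlation and 0 with an estimated one, where each had an adjusted p of 0.597 (0.603 for muscle). piRNA and germline genes had negative values. All 17 germline piRNA factors (median −0.46, camera adjusted p = 6.11e-05), all 14 nuclear silencing genes (−0.48, 0.000462) and all 16 germline markers (−0.51, 0.0013) were negative, as were 10 of 13 biogenesis genes (−0.41, 0.0118). vas, a germline helicase, had −0.39 and was lower in 6 of 6 lines, and osk, the posterior determinant of the egg, went from 814 to 441 CPM and was lower in 6 of 6. All 19 replication genes were negative too (−0.65, 0.000479), with the phosphatase gene stg at 240 against 400 CPM. Eggshell and yolk genes had 19 of 22 negative members and a median of −1.40 (0.0103), with the chorion gene Cp38 at 2030 against 2950 CPM and Yp3 higher by 1.31. The targeted genes passed with 0.0377, and 0.0851 without the line as a block. Immune effectors (14 tested, median 1.07, 0.0103) and muscle markers (11 of 11 positive, 0.55, 0.0455) were higher, with Drs, an antifungal peptide gene, at 153 ± 219 against 6.17 ± 7.95 CPM and higher in 6 of 6 lines. Of the members of these 9 lists 0 were called over all genes by edgeR. DESeq2 called members that included Drs (log2 fold change 5.96, adjusted p = 3.91e-06) and the silencing gene CG14438 (−0.54, 0.0438). By edgeR adjusted over the list alone, 2 targeted genes were lower and 0 members of the other lists passed.

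Several of these calls depended on FlamBG and FlamKG. With the other 4 lines alone, targeted genes (median −0.50, 0.0253), biogenesis (−0.18, 0.00573) and germline piRNA factors (−0.28, 0.000676) kept their calls at smaller medians for the latter 2, while silencing (0.0624), eggshell (0.384), germline markers (0.384), immune effectors (0.384) and replication (0.919) did not. Muscle markers were then lower (−0.34, 0.000676), as were hemocyte markers (−0.38, 0.0253) and follicle cell markers (−0.37, 0.00111). With an estimated correlation 0 lists passed in these 4 lines, with an adjusted p of 0.522 (0.695 for follicle cell markers). In all 6 lines the lists not past the threshold were follicle cell markers (0.0683), with shg, the E-cadherin gene, at 256 against 370 CPM, Hedgehog (median −0.30, mean 0.04, 0.752), ecdysone response (0.19), heat shock (median 0.86, 0.133), the siRNA pathway (0.102), apoptosis (0.211), CncC (0.211) and hemocyte and fat body markers (0.168).

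**Figure D4:**
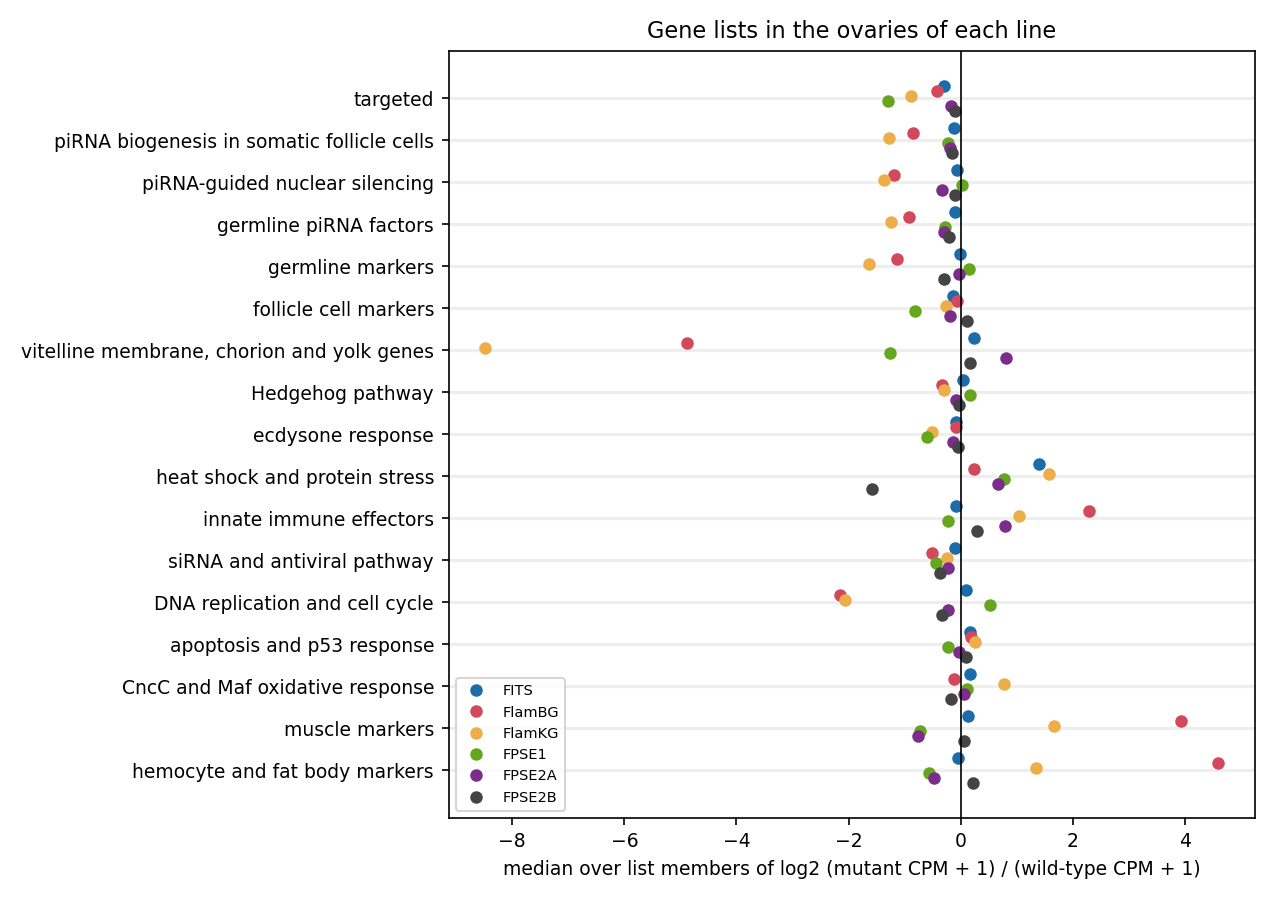
Median log2 ratio of mutant to wild-type ovary (horizontal axis, prior of 1 CPM) of 17 gene lists, with 1 coloured point per fly line. Eggshell and yolk genes lie at −8.48 in FlamKG and −4.88 in FlamBG, and between −1.27 and 0.81 in the other lines.

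Single lines differed in how many genes were over 4-fold apart between the mutant and wild-type library, with no replicate check. There were 53 higher and 31 lower in FITS, 998 and 246 in FlamBG, 1239 and 305 in FlamKG, 76 and 25 in FPSE1, 90 and 1 in FPSE2A, and 9 and 6 in FPSE2B. The chorion genes Cp38 (0.157 against 8540 CPM, log2 ratio −12.85), Cp36 (−11.50) and Cp19 (−9.97) were the lowest in FlamKG, and Cp15 (0.663 against 1740 CPM, −10.03), Cp18 and Cp38 in FlamBG. The highest were betaTry, a trypsin gene (9150 against 0.657 CPM), Bace and Mal-A1 in FlamKG, and the stress peptide gene TotA (6700 against 1.02 CPM), CG16826 and TotC in FlamBG. In FITS they were Osi7 (107 against 0.0866 CPM), CG43090 and Osi6, with Bace (0.43 against 294 CPM), betaTry and Dh31 lowest. In FPSE1 they were CG18404 (7.69), CG43090 and CG17633, with Mur11Da (−3.93), flam (−3.22) and CG31928 (−3.16) lowest. In FPSE2A they were Jon25Biii (225 against 0.609 CPM), CG17571 and CG10472, with Mal-B1 (−2.59), Cyp4g1 and Hml lowest. In FPSE2B they were CG43090 (4.17), CG13323 and LysE, with Jon25Biii (−3.62), LManVI and CG31343 lowest. Median log2 ratios of replication genes were −2.16 in FlamBG and −2.07 in FlamKG, those of muscle markers 3.92 and 1.66, and those of hemocyte and fat body markers 4.59 and 1.34.

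Ovary miRNAs gave no call. limma called 0 of 68 miRNAs tested on log2(RPM + 10), with 0 at an unadjusted p under 0.05, a lowest adjusted p of 0.96 and a median log2 fold change of −0.25 (n = 6 lines). That median was −0.05 when scaled to the miRNA total, and with 1 line left out it lay between −0.44 (without FITS) and 0.02 (without FPSE2A), so its sign was not stable. Without FlamBG, 7 had an unadjusted p under 0.05 and the lowest adjusted p (limma) was 0.0971. FlamBG and FlamKG ran in opposite directions for some miRNAs, chosen after their values were seen. mir-994 was at 707.7 (mutant) and 7.77 RPM (wild type) in FlamBG, against 9.58 and 1706 in FlamKG. mir-956 was at 117.4 and 2505 in FlamBG, against 24520 and 127.2, while mir-14 was lower in both mutants. Such changes cancel in the mean over lines. In long RNA these mutants correlated most with each other (r = 0.899), and the cause was not tested. By list, the median was −0.29 for the let-7 complex (3 tested), −0.41 for ovary-enriched miRNAs (6), 0.17 for the 1 member tested of the maternal-zygotic cluster, −0.17 for muscle or neuron miRNAs (2), −0.44 for the miR-310 family (6) and −0.19 for the miR-2 family (5). miRNAs made up 22382 to 102496 RPM of these libraries.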

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

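Of the tests below, those of ovary RNA and of a knockdown response were chosen after the antisense shares were seen.

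In OSS cells 12.36% of unique reads lay antisense to genes in siPiwi 2 and 9.27% in siTj 2, above all siGFP libraries, the highest of which held 4.81%. Antisense reads took no part in the comparisons of genes, but any sense reads of the same origin did. RNA carried over from whole ovaries would bring at most the ovary share, and the highest of the 12 ovary libraries held 7.32%, below both. A response to the loss of Piwi or TJ would raise the other libraries of these knockdowns too, and the highest of those 4 held 4.52%, below the highest siGFP library. Genomic DNA in both libraries stays open. In 2822 genes chosen for almost no reads in the other 10 libraries, reads fell on both strands alike (sense share 51.4% in siTj 2 and 51.3% in siPiwi 2). The sense share there lay between 45.8% and 61.5% over all 12 libraries, so it does not set these 2 apart. The rate per kb there gives 34.2% of the added antisense reads in siPiwi 2 and 39.1% in siTj 2, and a lack of strand in part of the library was not tested. Without this pair of libraries the median log2 fold change of muscle markers after siTj was 0.36 against 2.22. That of piRNA biogenesis genes was −0.56 against −0.57.

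Among the 6 mutant ovary libraries, FITS stood apart from the others with 353 CPM of piwi, 310 CPM of tj and 154 CPM of ci, each the highest. The FITS wild-type library was also the highest of the 6 wild types for these genes (433, 387 and 177 CPM), so the high level was not particular to the mutant. The log2 ratio of ci between mutant and wild type stood apart in FPSE1 at −1.29. The median log2 ratio of CncC genes stood apart in FlamKG at 0.77, and that of hemocyte and fat body markers in FlamBG at 4.59. The gap to the nearest library was compared with the range in 37 groups of 6 by Dixon's test, and 6 groups passed its critical value. Chance gives about 1 in 20 such groups, or 1.85 of 37. No explanation of these 6 values was tested.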

How the results depend on the processing

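Of the values under alternatives that summarise a comparison, 106 stayed on their side, 46 moved and 3 newly passed. Of those for single genes, 1327 stayed, 193 no longer passed, 21 moved, 9 changed sign and the rest newly passed. The cause was not tested where none is given. Fits without the pair siPiwi 2 and siTj 2, DESeq2 with pairing, exon reads and reads with several positions were chosen after seeing the data. For siTj, 5 genes became 211 with DESeq2, 1 with RLE scaling, 9 without a filter, 1 with only the 2 groups, 9 with exon reads, 1 with reads of several positions, 22 without the pair, 377 in the paired fit with the replicate block, 744 in the paired fit without the pair, 1228 in DESeq2 with pairing, and 0 to 2 with 1 library left out. Of the 377, 352 were among the 744 in the same direction, 165 among the 211 and 377 among the 1228. For siPiwi, 0 became 3 with DESeq2, 4 in the paired fit without the pair and 11 in DESeq2 with pairing. For siCi, 0 became 2 with DESeq2 and 14 in DESeq2 with pairing. For siTj against siPiwi, 0 became 80 with DESeq2, 2 without a filter, 73 in the paired fit, 3 without the pair, 477 in the paired fit without the pair, 446 in DESeq2 with pairing, and 0 to 6 with 1 library left out. Genes shared by siTj and siPiwi numbered 2 with DESeq2, 1 in the paired fit without the pair and 5 in DESeq2 with pairing. In the paired fit without the pair 1 more gene was called in opposite directions.

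Of 68 list tests in OSS cells 23 passed, 26 in the paired fit with the replicate block, 0 with an estimated correlation (lowest adjusted p 0.26), 17 to 26 with 1 library left out, 11 without the pair and 13 in the paired fit without the pair. In ovaries 9 of 17 lists passed, 0 with an estimated correlation, 8 to 11 with 1 line left out and 8 without the line as a block. DESeq2 called 357 ovary genes. With 5 CPM as the prior, the log2 ratio of flam was −2.32 in FlamKG and −2.88 in FPSE1, since a larger prior shrinks low values.

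With reads of several positions, flam had 0.46 after siPiwi and 1.26 in ovaries. After siPiwi, armi lay between −1.06 and 0.10 with 1 library left out, 0.01 without siGFP 3 and 0.06 without the pair. After siCi, piwi lay between −0.58 and 0.01 (without siCi 1), and tj between −0.80 and 0.11 (without siGFP 1), with 0.01 without siCi 2 and without siCi 3.

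Of the 5 genes lower after siTj, 2 had a TJ peak within 1 kb (exact p = 0.0834), 2 within 500 bp (exact p = 0.0587) and 3 within 2 kb (exact p = 0.0183), so the p of 5 genes turned on 1 gene. Within 1 kb, 53 of the genes lower in the paired fit had one, and 92 in the paired fit without the pair. The share of siGFP H3K4me3 summits found in siTj was 23.9% within 100 bp, 42.9% within 500 bp and 52.1% within 1 kb. For H3K9me3 it was 21.9%, 41% and 54.9%, and 26.9% in the upper 50% by score. A wider window can only raise these shares. No paired analysis was possible because OSS miRNA values were pooled, each knockdown had 1 Cut&Run library, and the TJ peaks were 1 list. Not run were DESeq2 and RLE for miRNAs, which had no counts, library-level alternatives for OSS miRNAs, and the stronger TJ peaks, since that list has no score. At the depth and spread of the unpaired OSS test, 0% of simulated 2-fold and 34% of 4-fold changes were found among genes with high counts. Smaller changes were therefore not detectable.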

Other observations

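The comparison of H3K9me3 with TJ peaks, its shares by score, the draws matched on score, the ovary genes named from DESeq2, the test of late egg chambers and the use of the interval in judging the shared direction of OSS cells and ovaries were chosen after their values were seen.

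Of 186 H3K9me3 summits of siGFP cells within 1 kb of a TJ peak, 10 had a summit in siTj (5.38%, interval 2.61 to 9.66), against 59.1% and 40.9% in the Plain libraries. In 10000 draws of other summits matched on score the median share found in siTj was 28.0%, with a lowest of 17.7% and a highest of 39.2%. The share was 11.9% at 1 to 5 kb, 17.2% at 5 to 20 kb and 35.3% over 20 kb from a TJ peak. Near gene starts over 5 kb from a TJ peak it was 15.0% (12.1 to 18.3), so summits near gene starts were also found less often away from TJ peaks.

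In ovaries DESeq2 called several genes that were higher in the mutant of all 6 lines. Send1, which encodes an endopeptidase of the spermatheca, was at 20.4 and 0.0742 CPM in FITS mutant and wild type, 651 and 0 in FlamBG, 479 and 8.47 in FlamKG, 40.6 and 0.0435 in FPSE1, 38.7 and 8.38 in FPSE2A, and 16.1 and 0.15 in FPSE2B (DESeq2 adjusted p = 4.52e-10, log2 fold change 7.56, SE 1.01). CG43074 (5.94, SE 0.718, 1.59e-12), CG43090 (8.0, SE 1.1, 1.07e-09) and CG32834 (6.98, SE 0.976, 2.41e-09) were higher in all 6 lines too. edgeR gave each an adjusted p of at least 0.436. Whether these reads came from ovary cells or from other tissue in the libraries was not tested.

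In the mutant ovaries of FlamBG and FlamKG, 19 chorion and vitelline genes had median log2 ratios of −5.26 and −8.73. Dilution by RNA of other tissues alone would lower germline markers as much. Their median lay 4.13 (FlamBG) and 7.1 (FlamKG) log2 units above that of the eggshell genes. The lower limits were 2.84 and 5.72, from 2000 bootstrap draws over genes, which hold no spread between ovaries. Germline markers themselves had medians of −1.13 and −1.63, and muscle markers 3.92 and 1.66. Dilution could thus be a part, but not the whole, of the pattern in these libraries. Fewer late egg chambers in both lines stay open as an explanation. 100% of the 19 genes lay below −1 in both lines, which restates the pattern and decides nothing. Each line had 1 mutant library, so the flamenco allele, the age of the flies and the state of the ovaries were not parted.

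siTj had fewer H3K4me3 and H3K9me3 summits than siGFP. A loss of H3K4me3 at sites bound by TJ stays open. Of siGFP summits within 1 kb of a TJ peak 40% (36.5 to 43.6) were found in siTj against 37.2% elsewhere. Summits near TJ peaks had higher scores, though (median 24.3 against 18.2). In 10000 draws matched on score the median was 42.8%, with a lowest of 37.6% and a highest of 47.7%. The 40% lay below the median of the draws and within their full range. A lower yield of the siTj libraries stays open too. Among the 25% of siGFP H3K4me3 summits with the highest scores the share found in siTj lay 15.2 percentage points below that in the closer Plain library, between the bounds set for either answer. For H3K9me3, which that test did not cover, the share in siTj among the 25% with the highest scores was 55.8%, against 60.9% and 56.5% in the Plain libraries, and among the 25% with the lowest scores 14.3%, against 50.1% and 28.6%. A lower yield would give such a loss mainly of weak summits, so it stays open for both marks. A biological effect of siTj on the marks was not separable with 1 library.

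A further hypothesis was that genes lowered by siTj in OSS cells would also fall in mutant ovaries. Of 151 genes lower in the paired fit 50.3% (42.1 to 58.6) had a negative log2 fold change in mutant ovaries, against 59.5% of the 9556 others and 43.7% (37.0 to 50.6) of the 215 higher. The share met neither the bound for the hypothesis (over 60%) nor that against it (at most 50%, beyond the spread). Its interval lay below 60% and below the 59.5% of the others, so the mean over lines did not show a shared fall. By line, the share was above that of the others in FITS (54.3% against 45.5%) and FPSE1 (53.6% against 49.7%). It was below in FlamBG (52.3% against 62.2%), FlamKG (49% against 55.5%), FPSE2A (43% against 54%) and FPSE2B (44.4% against 53%). The lines disagreed, so the hypothesis stays open for single lines.

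Other splits of the libraries were tried for each comparison. With 10 splits of 6 OSS libraries the share of splits as large as the real one cannot go under 0.05. Lists were adjusted there within each comparison alone, so their real counts differ from those over all comparisons. A real count of 0 is reached by every split and decides nothing. For siTj, 1 of the 10 splits called as many genes unpaired (real 5, highest other 0), 1 in the paired fit (377, other 0) and 1 for lists (9, other 8). For siPiwi these were 10 (0, other 0), 10 (0, other 90) and 5 (5, other 10), and for siCi 10 (0, other 0), 10 (0, other 3) and 5 (1, other 6). For siTj against siPiwi they were 10 (0, other 577), 1 (73, other 20) and 4 (8, other 10). The split with 577 set siPiwi 1, siPiwi 3 and siTj 3 apart from siPiwi 2, siTj 1 and siTj 2, and the split with 90 set siGFP 1, siGFP 2 and siPiwi 1 apart from the rest, so the samples hold structure other than their group. Among splits that part every pair of replicate numbers, as the real one does, the highest other called 0 genes. In ovaries 100 of 462 possible splits were used. They were all 32 that part every line, the real one included, and a sample of others that part at least 1 line. Counts out of 100 are thus not shares of all possible splits. The gene count was reached by 100 of them (real 0, highest other 6261), the miRNA count by 100 (real 0, other 21) and the list count by 18 (real 9, other 11), so chance was not excluded for lists, and the counts of genes and miRNAs decide nothing. The split with 6261 points to structure among the ovary libraries. Among the 32 splits that part every line, the highest other was 0 genes and 7 miRNAs, and 7 had as many lists.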
